A study of Mus musculus with 13 samples.

How the data were processed

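RNA was sequenced from CD45-positive cells sorted by flow cytometry from subcutaneous EL4 tumours, EL4 being a mouse T-cell lymphoma line that itself belongs to the CD45-positive lineage. Per the labels' protocols, 500000 EL4 cells carrying either a vector or a knockout of PSGL1 were injected per mouse, tumours were taken about 20 days later, and libraries were made from total RNA with a NEBNext Ultra RNA kit. The groups came from the sample titles and held 7 vector and 6 PSGL1_KO libraries. The titles number the replicates without saying that each came from its own mouse, so p-values measure the spread between these libraries. The name of the cell line carries a running number in the treatment labels and is EL4 throughout the titles, and the titles were used.

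The authors deposited 1 file of raw read counts per gene ID for each sample. HISAT2, SAMtools, HTSeq and the build mm10 are named in the submitters' processing notes, and their versions, the annotation release and the strand setting are not given in the sources used here. Each deposited file held 56923 versioned gene IDs and the 5 HTSeq summary rows, which were kept out of library sizes and tests. Reads over no annotated feature made up 67.3% to 75.4% of all rows' totals, reads with more than 1 alignment 7.71% to 13.6%, low-quality alignments 3.55% to 5.67%, unaligned reads 1.05% to 3.47% and ambiguous reads 0.31% to 0.47%. Gene IDs received 10.5% to 12.5%, or 3710817 to 5712566 counts per library. Between libraries of a group, the lowest mean chi-square per gene ID was 3.22, where sampling noise alone gives about 1, so no pair agreed within sampling noise. Vector replicates 3, 4 and 7 lay closest to each other, at 3.22 to 3.98, and every other pair of vector libraries was at 9.79 or more.

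Gene symbols came from a table of gene IDs and symbols, in which 52073 of the 56923 IDs matched without their version. Coordinates are those of GENCODE M21 on GRCm38, the assembly also called mm10. Of the 52073 matched IDs, 52036 carried a higher version number than in GENCODE M21, and 4850 IDs were absent from it. Genes that nearly all cells use were close to 0 over most of the genome: 313 housekeeping genes outside the stretches described next had a median of 0.33 CPM (counts scaled to a library total of 1e6). Names of nuclear genes were therefore used only where the counts bore them out, a restriction chosen after the data had been seen. A 2-state hidden Markov model ran along each chromosome over mean CPM classes of protein-coding genes, with limits of 2, 20 and 100 CPM and with housekeeping genes left out. A stretch was kept if it had a posterior above 0.99, a length of at least 5 Mb, at least 20 genes and no housekeeping gene under 20 CPM. The 4 stretches kept span 106 Mb, on chromosome 4 from 3549041 to 59801589, chromosome 6 from 3457096 to 17341452, chromosome 15 from 9071260 to 38078854 and chromosome 18 from 3266048 to 10045119. The stretch on chromosome 18 held 0 housekeeping genes and so lacks that check. All 7 housekeeping genes inside the others were above 20 CPM, a condition of keeping a stretch. In the stretches 54.1% of protein-coding IDs reached 20 CPM, against 2.6% of long noncoding, antisense and pseudogene IDs, which the model had not used. Outside the stretches these shares were 17.1% and 3.1%. The model chose the stretches by the protein-coding levels, so the first share follows from that choice, and the second does not set the stretches apart. IDs in the stretches and on the mitochondrial chromosome are called name-checked genes, and they held 8.7% and 15.4% of gene counts. The 37 mitochondrial IDs were included without the model or the housekeeping condition, so their names were not checked in this way. No other ID was given a name, and none was moved to another gene.

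The comparison was fitted with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood test with robust dispersion, TMM factors, the filterByExpr filter and the group as the only term. It is two-sided, with Benjamini-Hochberg adjustment over the 10422 IDs kept, of which 430 were name-checked, and a threshold of 0.05. The log2 fold change (log2FC) is PSGL1_KO minus vector, given with its standard error, and levels are TMM-normalised CPM with the SD over libraries. The square root of the common dispersion was 29.4%. On counts simulated for this comparison, with 200 of the genes changed, the test recovered 74 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 1 false call among 10040 unchanged genes tested. Of the 2-fold changes, 32 of 50 were recovered at 5.29 to 31.3 CPM and 42 of 50 at 32.4 CPM or more. Every simulated gene had the common dispersion and no other structure among the libraries of a group, so these rates may not hold for the real libraries.

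Before the data were examined, 40 gene lists were written from general knowledge, and both stored copies of them matched for 40 of 40. A list was to be tested if 5 or more members were measured. Counting only name-checked members, 1 list qualified, that of the protein genes encoded by mitochondrial DNA. It was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and by an exact permutation test of its score over 1716 assignments of the libraries. The rule for named genes, also written beforehand, was the knockout target first, then a fixed panel of 20 genes, then up to 12 genes in each direction with adjusted p below 0.05, an absolute log2FC of at least 1, a mean of at least 5 CPM in the higher group and no symbol of the Gm, Rik, AC, AL or CT kinds or of a pseudogene, and finally up to 4 members per described list with the smallest p. The last 2 parts were applied to name-checked genes only.

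Alternatives covered DESeq2 1.42.0, limma-voom with quality weights, other scaling factors, other filters, a fold threshold, the replicate number as a block, the first digit of the number in the file names (3 or 7) as a covariate, and each library left out. The planned covariate of T-lineage genes was not run, because 0 members of that list were name-checked. Chosen after the data had been seen were a scaling on the name-checked nuclear genes, fits within each file-number group, wider stretches, and every gene name taken at face value. The fits within file number 3 compared 2 vector with 2 PSGL1_KO libraries, so their small p-values rest on little replication. Genes on opposite strands with overlapping exons cannot be told apart where the strand setting is unknown.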

Results

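RNA sequencing of sorted CD45-positive cells from subcutaneous EL4 lymphomas compared 7 libraries from tumours of vector cells with 6 from tumours of cells lacking PSGL-1. PSGL-1, encoded by Selplg, is a selectin ligand of leukocytes. The title of the series poses the question of whether tumour PSGL-1 restrains phagocytosis by macrophages through the integrin LFA-1. The libraries held 3710817 to 5712566 counts over gene IDs, with a median of 4584464.

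The targeted gene could not check the labels. The ID named Selplg (ENSMUSG00000048163.14, GRCm38 chromosome 5, 113818536 to 113832644) lies outside the stretches in which gene names matched their counts. It had 11, 17, 42, 44, 37, 53 and 31 counts in vector replicates 1 to 7 and 7, 3, 35, 41, 56 and 63 counts in PSGL1_KO replicates 1 to 6. Other IDs outside those stretches carried names whose genes are abundant in nearly every cell or in macrophages, and they had few counts. The ID of Eef2, a translation elongation factor, had at most 3 counts in any library, and that of beta-actin, Actb, at most 22. The IDs of Cd74, C1qa and Adgre1, which antigen-presenting cells and macrophages express, had 0 counts in all 13 libraries. Inside the stretches, Rps20, a ribosomal protein gene, averaged 7024 CPM and Pabpc1, which encodes the poly(A)-binding protein, 6930 CPM. None of the 20 genes of the fixed panel, which included Itgal and Itgb2 for the chains of LFA-1 and Cd47 and Sirpa for a phagocytosis checkpoint, had a checked name, and 7 of them had at most 3 counts in every library. Their values are not interpreted here.

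**Figure D1:**
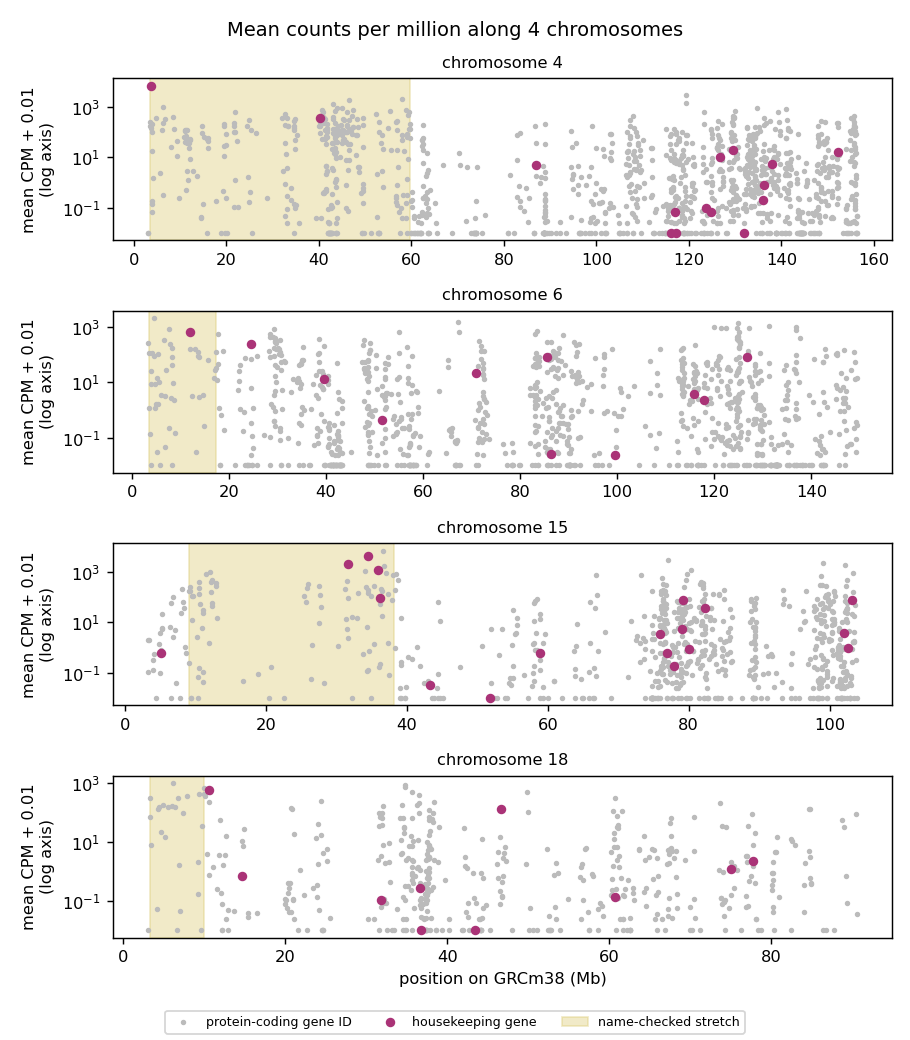
Mean CPM plus 0.01 (log axis) of protein-coding gene IDs against their GRCm38 start position in megabases on chromosomes 4, 6, 15 and 18, with housekeeping genes as large points and the 4 name-checked stretches shaded. The 7 housekeeping genes inside the shading were all above 20 CPM, while most of those elsewhere were below it.

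Of 430 name-checked genes tested, 81 were higher and 24 lower in PSGL1_KO, and Lyn, Cd72 and Tfec were among the higher ones. Among the 339 that code for protein, 71 were higher and 9 lower. Most of the excess came from the stretch on chromosome 4, with 57 higher and 5 lower of 247 tested. Chromosome 15 gave 12 and 8 of 84, chromosome 6 gave 9 and 4 of 44, and chromosome 18 gave 3 and 2 of 33. The mitochondrial chromosome gave 0 and 5 of 22. Lyn, a Src-family kinase of myeloid and B cells (GRCm38 chromosome 4, 3678115 to 3813122), rose from 58.7 ± 10.8 CPM (SD, n = 7) to 246.7 ± 56.3 CPM (SD, n = 6), a log2FC of 2.07 ± 0.18 (SE) with adjusted p = 2.1e-07 in the edgeR test. Cd72, an inhibitory lectin of B cells and some macrophages (chromosome 4, 43446462 to 43454628), rose from 47.8 ± 17.6 to 230.3 ± 70.9 CPM, a log2FC of 2.27 ± 0.26 with adjusted p = 6.2e-06. Tfec, a transcription factor of the macrophage lineage (chromosome 6, 16833373 to 16898441), rose from 8.15 ± 2.21 to 21.7 ± 4.27 CPM, a log2FC of 1.41 ± 0.21 with adjusted p = 0.00011. In Lyn, Cd72 and Tfec alike, 6 of 6 PSGL1_KO libraries were above every vector library. Beside them, 6 of 13 markers of stromal cells were higher in PSGL1_KO and 0 were lower, among markers listed after the data had been seen, some of them already known to be high.

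Of the 29 genes that met the rule for the higher direction, the 12 with the smallest adjusted p were named. Rragd, a Rag GTPase that acts at the lysosome, had a log2FC of 1.94. Ggh, a lysosomal gamma-glutamyl hydrolase, had 1.19, and Ugcg, which makes glucosylceramide, had 1.07. Car8, a carbonic anhydrase relative without enzyme activity, rose from 4.94 ± 2.93 to 49.4 ± 7.93 CPM. AI427809, a noncoding RNA with an accession as its name (chromosome 4, 53261356 to 53270232) had the smallest p of the name-checked genes and rose from 18.8 ± 4.11 to 217.0 ± 51.1 CPM, a log2FC of 3.53 ± 0.20 with adjusted p = 1.1e-09. The remaining 4 were Asph, a hydroxylase of the endoplasmic reticulum, with a log2FC of 1.46, Mdfic, a transcriptional regulator, with 1.17, Tesk1, a kinase of actin regulation, with 1.80, and Il11ra1, the interleukin 11 receptor, with 1.27. In all 12 genes, 6 of 6 PSGL1_KO libraries exceeded every vector library, and adjusted p was at most 0.00047. Exons of Tesk1 and Cd72 overlap on opposite strands, as do those of Asph and Clvs1 and of Il11ra1 and Ccl27a, and their reads cannot be told apart. Il11ra1 also has a close copy nearby, so its count is uncertain.

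Asparagine synthetase and a T-cell adaptor were lower in the PSGL1_KO tumours. Asns (chromosome 6, 7675169 to 7693254) fell from 1085 ± 163 to 512.8 ± 118 CPM, a log2FC of -1.08 ± 0.17 with adjusted p = 0.0002. Sit1, a membrane adaptor of T-cell receptor signalling (chromosome 4, 43482081 to 43483734), fell from 30.3 ± 9.37 to 15.1 ± 2.43 CPM, a log2FC of -1.01 ± 0.21 with adjusted p = 0.0026. In both, 6 of 6 PSGL1_KO libraries were below every vector library. The 9 genes that met the rule for this direction also included the noncoding RNA Dlx6os1, with a log2FC of -1.48 and adjusted p = 0.0031, and Spef2, a sperm flagellar gene, with -1.10 and adjusted p = 0.043. The other 5 were the mitochondrial transfer RNA genes mt-Tq, mt-Ta, mt-Tw, mt-Ty and mt-Te, with log2FC from -1.95 to -1.13. None of these 5 passed within the libraries whose file number starts with 7, with log2FC from -2.05 to -1.14 and adjusted p from 0.071 to 0.12. Vector replicate 5 had the highest value of its group in mt-Tq, mt-Ta, mt-Tw, mt-Ty and mt-Te. Without that library mt-Ty, mt-Te and Spef2 no longer passed, with adjusted p of 0.07, 0.11 and 0.057, and the log2FC of mt-Ty was -0.71. Spef2 also did not pass without any one of vector replicates 1, 2 and 3 or PSGL1_KO replicates 3, 4, 5 and 6, with adjusted p from 0.0503 to 0.108. For mt-Ty this held without vector replicate 6 or PSGL1_KO replicate 1, 2, 4 or 5, and for mt-Te without vector replicate 1, 2 or 6 or PSGL1_KO replicate 1, 3, 4, 5 or 6, with adjusted p from 0.052 to 0.11.

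**Figure D2:**
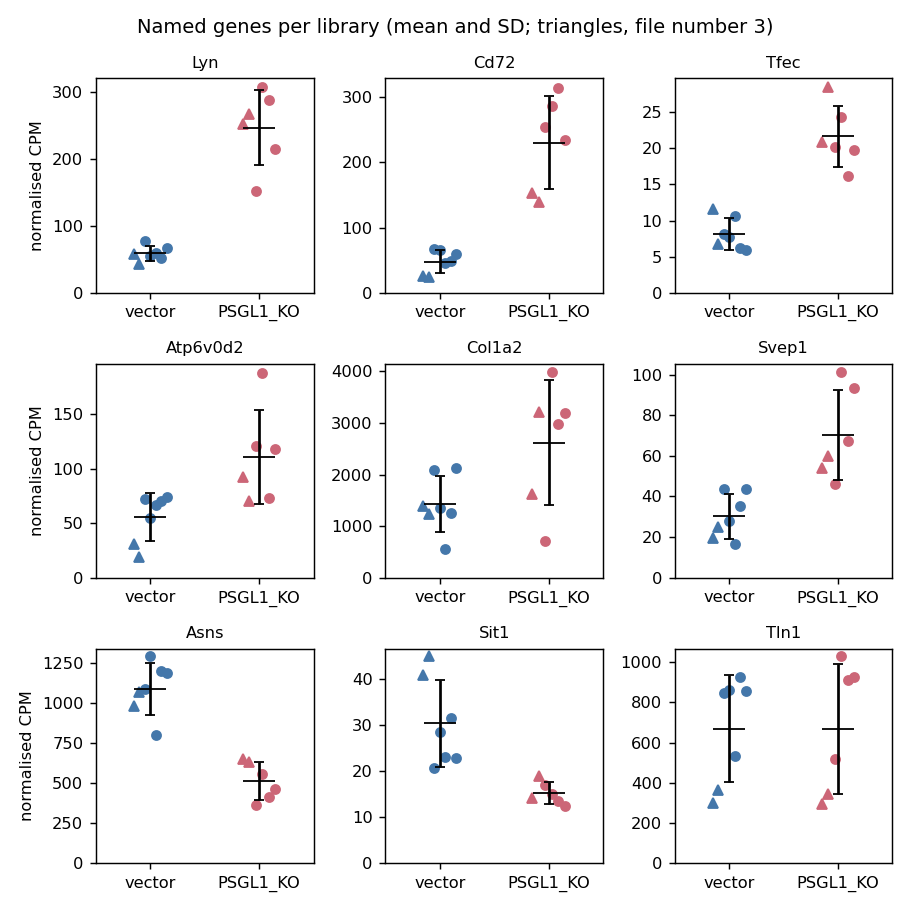
Normalised CPM of 9 genes in each of the 7 vector and 6 PSGL1_KO libraries, with the mean (line) and SD (bars). Triangles are libraries with file numbers starting with 3 and circles those starting with 7. Lyn, Cd72 and Tfec are higher and Asns and Sit1 lower in all 6 PSGL1_KO libraries than in every vector library, while the ranges of Tln1 overlap.

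The fixed lists reached the name-checked genes with few members. Of 40 lists, 14 had at least 1 such member tested, 27 genes in all, of which 5 passed over all IDs tested. Adjusted over these 27 genes together, 6 passed, the additional one being mt-Nd4l, with only 8.29 CPM in vector and 3.75 CPM in PSGL1_KO libraries. In the phagocytic signalling list the single member was Lyn, which rose. In the phagosome and lysosome list it was Atp6v0d2, a proton pump subunit of macrophages and osteoclasts, which rose from 55.4 ± 22 CPM to 110.5 ± 43.4 CPM, a log2FC of 1.00 ± 0.29 with adjusted p = 0.025. Without PSGL1_KO replicate 4 Atp6v0d2 did not pass, with adjusted p = 0.085, nor did it with scaling on name-checked nuclear genes, with a log2FC of 0.81 and adjusted p = 0.087. In the hypoxia list Car9, a carbonic anhydrase induced by low oxygen, rose with a log2FC of 1.27 and adjusted p = 0.0015, and its exons overlap an antisense gene. In the list of PSGL-1 and selectin ligand glycosylation, B4galt1, a galactosyltransferase, rose with a log2FC of 0.60 and adjusted p = 0.0032, and C1galt1, which makes core 1 O-glycans, had -0.47 with adjusted p = 0.2. C1galt1 passed once the first digit of the file number was a covariate, with a log2FC of -0.47 and adjusted p = 0.0026, and within libraries whose file number starts with 7 (-0.39, adjusted p = 0.017) or with 3 (-0.63, adjusted p = 0.0061) and with scaling on name-checked nuclear genes (-0.68, adjusted p = 0.022). Asns was the member of the unfolded protein and stress list.

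The single member of the LFA-1 activation list did not differ detectably. Tln1, which encodes talin 1, a protein that binds integrin tails, averaged 669.5 ± 265 CPM in vector and 670.1 ± 324 CPM in PSGL1_KO libraries. Its log2FC was 0.00 with a 95% interval from -0.62 to 0.63 and adjusted p = 0.998, and its sign turned with the scaling and without any one of vector replicates 1, 2 and 5 or PSGL1_KO replicates 4, 5 and 6. Its exons overlap those of Creb3 on the opposite strand, so their reads cannot be told apart, and the ID of Creb3 had a log2FC of 0.65 with adjusted p = 0.0047. Other single members that did not pass were Abca1 of lipid handling (log2FC 0.36), Pax5 of B cells (0.69), Ddx58 of the type I interferon response (0.39), Tox of T-cell checkpoints (-0.23) and Ccne2 of the cell cycle (-0.12). In oxidative phosphorylation Ndufa4 had -0.22 and Cox6c 0.23, and neither passed. Exons of Cox6c, Tox and Ccne2 also overlap a gene on the opposite strand. Within file number 7 alone Ndufa4 had -0.46 and Tox -0.41, and both passed, with adjusted p of 0.011 and 0.032, while within file number 3 alone they had 0.0085 and 0.25 and did not. The difference between the file numbers did not pass in either, with adjusted p of 0.3 and 0.15. Within file number 3 Abca1, Ddx58 and Pax5 passed, with adjusted p of 0.027, 0.0029 and 0.045, and with the file-number covariate Abca1 and Ddx58 did, with adjusted p of 0.028 and 0.026. Col1a2, a collagen gene of fibroblasts, was abundant in this CD45-positive sort, at 1428 ± 536 CPM in vector and 2617 ± 1209 CPM in PSGL1_KO libraries, a log2FC of 0.87 with adjusted p = 0.083. It passed within file number 3, on 2 libraries per group, with a log2FC of 0.91 and adjusted p = 4.7e-05. There it had 1387 and 1240 CPM in the vector libraries and 1618 and 3219 CPM in the PSGL1_KO libraries. Within file number 7 it did not pass, with 0.87 and adjusted p = 0.31. Without PSGL1_KO replicate 3 it passed, with a log2FC of 1.07 and adjusted p = 0.013, and so did Abca1, with adjusted p = 0.027.

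Protein genes of mitochondrial DNA had negative log2FC in 12 of 12 members, from -1.14 to -0.18, and 0 of the 12 passed in the edgeR test, either over all IDs tested or, for these 12 genes, adjusted over the list alone. The members mt-Nd4l and mt-Cytb had unadjusted p of 0.0096 and 0.018 there and passed with DESeq2, at adjusted p of 0.027 and 0.044. In the edgeR test mt-Nd4l passed without vector replicate 6 (adjusted p = 0.035), with the file-number covariate (0.037), within file number 7 (0.048) and with scaling on name-checked nuclear genes (0.029), where mt-Cytb also passed (0.027). Within file number 3 mt-Nd4l had -0.26 and mt-Cytb -0.16, and neither passed. Counts of mt-Nd4l were low, at 8.29 CPM in vector and 3.75 CPM in PSGL1_KO libraries. Its interval overlaps that of mt-Nd4, which had 11566 and 7737 CPM, so its values are uncertain. Vector replicate 7 had 22.5 CPM of mt-Nd4l and the other vector libraries 3.18 to 9.46 CPM, and without it the log2FC was -0.64 instead of -1.14, with adjusted p = 0.19. The mitochondrial list did not pass with camera, at p = 0.097, or p = 0.58 with an estimated correlation, nor with fry, at p = 0.38, so that 0 lists passed. The list score differed by -0.30 log2 units between PSGL1_KO (-0.16 ± 0.30) and vector (0.14 ± 0.68), with p = 0.43 in the exact permutation test. Mitochondrial IDs took 34.5% of the gene counts of vector replicate 5 and 11.6% to 16.2% of the other vector libraries. Without that library the list score difference was -0.07, and name-checked calls were 75 higher and 19 lower.

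Over all 10422 gene IDs tested, whatever their names, 940 were higher and 572 lower in PSGL1_KO at an adjusted p below 0.05, and 2889 had an unadjusted p below 0.05. Without vector replicate 5, which has a high mitochondrial share, 868 were higher and 537 lower. The first principal component, with 41.3% of the variance of the 2000 most variable IDs, separated the groups. The second, with 25.4%, separated libraries by the first digit of their file number. Vector and PSGL1_KO each had 2 libraries with a 3, and 5 and 4 with a 7. With the groups in the model, 4144 IDs differed between these file-number groups. Within the libraries of number 7 alone, 1205 IDs were higher and 1038 lower, and within those of number 3 alone 1312 and 1135. Name-checked genes gave 96 higher and 51 lower within number 7, and 124 and 25 within number 3. The difference between PSGL1_KO and vector itself differed between the file-number groups in 220 IDs, 10 of them name-checked. Lyn had a log2FC of 1.95 within number 7 and 2.41 within number 3, Cd72 had 2.25 and 2.59, Asns -1.31 and -0.64, and Sit1 -0.82 and -1.34. Of the genes named here, AI427809 alone passed the test of that difference, with 3.16 within number 7, 4.35 within number 3 and adjusted p = 0.027.

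The balance of directions depended on the scaling. With factors from the name-checked nuclear genes, chosen after the data had been seen, the median log2FC of all IDs moved to -0.21, calls over all IDs became 596 higher and 1174 lower, and those among name-checked genes 54 higher and 49 lower. The share of higher calls among name-checked genes was 52.4% with these factors and 77.1% with TMM over all IDs. Under these factors Lyn had a log2FC of 1.87, Cd72 2.10, Tfec 1.20, Asns -1.31 and Sit1 -1.21, and all 5 passed.

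**Figure D3:**
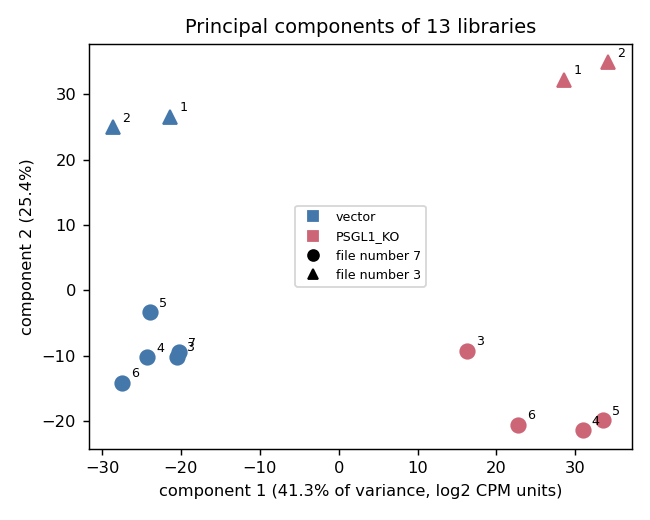
The first and second principal components of log2 CPM over the 2000 most variable gene IDs, which carry 41.3% and 25.4% of the variance, for 13 libraries numbered by replicate. The groups lie apart along the first component, and libraries with file numbers starting with 3 (triangles) and 7 (circles) lie apart along the second.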

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

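The tests of genome intervals, of pseudogenes and of stromal markers were chosen after the values had been seen. In groups of 6 or 7 libraries, 84 sets of values were examined for 1 library standing apart by Dixon's criterion, and 13 did so. Chance gives about 1 in 20 for independent sets. These sets share libraries and linked genes, so the 13 cannot be set against that rate.

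Of these 13, 9 were vector replicate 5 at the top of its group, for mitochondrial measures. Mitochondrial IDs took 34.5% of its gene counts (11.6% to 16.2% in the other vector libraries), and its mitochondrial list score was 1.61 (others -0.38 to 0.14). It had 80308 CPM of mt-Cytb, 29183 CPM of mt-Nd4, 28223 CPM of mt-Nd2, 305.9 CPM of mt-Tq, 39.8 CPM of mt-Ta, 38.1 CPM of mt-Tw and 71.8 CPM of mt-Ty. Vector replicate 7 stood apart with 22.5 CPM of mt-Nd4l. Vector replicate 2 had the lowest AI427809 of its group, 10.5 CPM (others 17.8 to 23.1 CPM). PSGL1_KO replicate 6 had the lowest Rragd, 13.4 CPM (the next lowest 21.7 CPM), and PSGL1_KO replicate 2 the highest Il11ra1, 303.3 CPM (others 130.1 to 179.2 CPM).

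Housekeeping genes were near 0 outside the 4 name-checked stretches. If reads shared with processed pseudogenes were the whole cause, families with few of them would be spared. Housekeeping genes other than ribosomal protein genes had a median of 0.317 CPM there, but they were not chosen for having few pseudogenes. This median therefore cannot decide that explanation. Another candidate explanation is that reads aligned to one build were counted over gene intervals of another. Of 69 low ribosomal protein genes, 16 could be brought onto an ID above 500 CPM by offsets sought for neighbouring genes together. The mean was 8.21 and the maximum 12 in 200 draws of other low genes of the same chromosomes. The permutation p was 0.005, the smallest these draws can give. A gene alone at its offset was counted too, so the 16 need not share offsets. The draws were matched by chromosome, but not by how many abundant IDs lay nearby. This test therefore cannot decide whether intervals were shifted, and it does not say which annotation was used.

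More name-checked genes were higher than lower in PSGL1_KO, at a ratio of 3.38. The excess lay mainly on chromosome 4, with 57 higher and 5 lower calls. Calls were 12 and 8 on chromosome 15, 9 and 4 on chromosome 6, and 3 and 2 on chromosome 18. It is therefore not a direction shown over the genome, and why the chromosomes differed was not tested. The mitochondria-rich vector library as the cause is argued against by a ratio of 3.95 without it. The split by file number is argued against as the whole cause by a ratio of 1.88 within number 7. The size of the excess still differed with the file number, at 65.3% higher calls within number 7 and 83.2% within number 3. Scaling remains open: the ratio was 1.1 with factors from the name-checked nuclear genes, although factors from a set of genes centre that same set near 0, so the excess may be one relative to the other gene IDs. RNA of stromal cells that escaped the sort also remains open, since a list of stromal markers scored 0.68 log2 units higher in PSGL1_KO but held genes already known to be high when it was written, so that score decides nothing, and its most abundant member, Col1a2, did not pass except within file number 3 or without PSGL1_KO replicate 3. Loss of PSGL-1 in the tumour cells stays among the open explanations. EL4 cells are themselves CD45-positive, so the sort does not part them from host cells, and their share in each library was not measured.

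Other splits of the same libraries gave fewer calls than the real one. Only 100 splits were drawn, and they treat the libraries as independent, which the titles do not state. Of 100 splits of the 13 libraries into 7 and 6, 1 gave as many gene IDs as the real one, the real one itself, with 1512 against at most 101 in the others. For name-checked genes it was likewise 1 split, with 105 calls against at most 6.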

How the results depend on the processing

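Fits within a file-number group, the scaling on name-checked nuclear genes and all settings of the name-checked counts were added after the data had been seen, and the cause of the changes below was not tested. Over all IDs, higher and lower calls were 1435 and 1254 with the file-number covariate, 1544 and 1257 with limma-voom, 580 and 190 with an absolute log2FC of at least 1, which removes calls by construction, and 596 and 1174 with the scaling on name-checked nuclear genes. Lower calls were 1038 within file number 7 and 1135 within file number 3, which hold fewer libraries. The labels do not say whether same-numbered libraries of both groups share more than a number. Their deviations correlated from -0.05 to 0.60 over 6 pairs, with pairs 3 and 5 under 0.1, and from -0.17 to 0.30 once the means of the file-number groups were removed. Of the 6 PSGL1_KO libraries, 2 correlated best with the vector library of their own number. With the replicate number as a block, 1176 IDs were higher and 962 lower. DESeq2 gave 1093 and 802, and the other scaling and filter settings stayed within 1.5 times of the reported counts. Leaving out each library in turn gave 753 to 1034 higher and 428 to 607 lower.

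Among name-checked genes, higher and lower calls were 122 and 45 with the file-number covariate. Higher calls were 124 within file number 3 and 41 with the fold threshold. Lower calls were 49 with the scaling on name-checked nuclear genes, 51 within file number 7 and 53 with limma-voom. Wider stretches gave 89 and 27, adjustment over the name-checked genes alone 94 and 30, and single libraries left out 67 to 88 and 19 to 29.

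The count of lists passing ranged from 0 to 1 as libraries were left out. In limma's camera the mitochondrial list passed without vector replicate 2 (adjusted p = 0.047), 4 (adjusted p = 0.035) or 7 (adjusted p = 0.0496) or PSGL1_KO replicate 2 (adjusted p = 0.046), and had an adjusted p of 0.73 without vector replicate 5. These use the preset correlation: with an estimated correlation, added after the data had been seen for single libraries left out, p was 0.48 to 0.89 and none passed, against p = 0.58 with all libraries and p = 0.38 with fry. The list score difference ranged from -0.37 to -0.07. With every gene name taken at face value, 28 lists could be scored and 0 passed. Names outside the stretches were not borne out by the counts, so this result decides nothing about those lists. The tally for named genes left out upper-quartile factors, the other filters, the removal of mitochondrial, haemoglobin and immunoglobulin genes, and limma-voom. Of 24 named genes that passed, 17 passed in all 20 alternatives in that tally. The others were mt-Tq, mt-Ta and mt-Tw, which did not pass with the block (adjusted p = 0.086, 0.11 and 0.06) or within file number 7, mt-Ty, mt-Te and Spef2, lost in 8, 10 and 8 alternatives, and Atp6v0d2, lost with the scaling on name-checked nuclear genes (adjusted p = 0.087) and without PSGL1_KO replicate 4. With the block C1galt1 and Pax5 passed (adjusted p = 0.025 and 0.033), and mt-Nd4l had -0.62. The direction turned in Tln1, which had -0.0104 with RLE factors, -0.0107 with DESeq2, -0.163 with the scaling on name-checked nuclear genes, -0.0254 within file number 3, and -0.16 to 0.15 over its alternatives. Within file number 3, mt-Nd2 had 0.26, Ndufa4 0.0085, Tox 0.25, Col15a1 -0.21 and Rps20, which had passed before, 0.0301. Cox6c had -0.0058 with the scaling on name-checked nuclear genes. Cav2 had -0.25 to 0.0473 as single libraries were left out.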

Other observations

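Some genes known from fibroblasts, endothelium and matrix were higher in the PSGL1_KO libraries of these CD45-positive sorts. After the data had been seen, 15 such markers were listed from the name-checked stretches, some of them already known to be high, and 13 could be tested. Of these, 6 were higher and 0 lower in PSGL1_KO. Svep1, a matrix adhesion protein, rose from 30.3 to 70.4 CPM, with a log2FC of 1.22 and adjusted p = 0.002. Tfpi2, a secreted protease inhibitor, had 1.30, Lpar1, a lysophosphatidic acid receptor, 1.15, Sdc2, a cell-surface proteoglycan, 0.99, Npr2, a natriuretic peptide receptor, 0.89, and Reck, an inhibitor of matrix metalloproteinases, 0.54. Cav1 (0.46), Cav2 (-0.07) and Col15a1 (0.26) did not pass. Sdc2, Npr2 and Reck did not pass with scaling on name-checked nuclear genes (adjusted p = 0.096, 0.11 and 0.15). Sdc2 did not pass within file number 7 (adjusted p = 0.092). Within file number 3, on 2 libraries per group, Tfpi2 and Npr2 did not pass (adjusted p = 0.051 and 0.27). Cav1 did there, with a log2FC of 0.81 and adjusted p = 0.00037. Sdc2 also did not without any one of vector replicates 2 to 7 or PSGL1_KO replicates 1, 2, 4 and 6 (adjusted p from 0.053 to 0.12), nor Npr2 without any one of vector replicates 1, 2, 4 and 6 or PSGL1_KO replicates 4, 5 and 6 (adjusted p from 0.06 to 0.12). Within file number 7 Cav1 had 0.03 with adjusted p = 0.96, and without PSGL1_KO replicate 2 it had 0.11 with adjusted p = 0.87. Sorting on CD45 would remove such cells, and macrophages can express some of these genes. A larger share of stromal RNA in the PSGL1_KO libraries is a hypothesis that these values leave open. The list score was 0.68 log2 units higher, which cannot test this hypothesis because some of the genes were known to be high when listed. Col1a2 missed the threshold with adjusted p = 0.083. It passed without PSGL1_KO replicate 3 (adjusted p = 0.013) and within file number 3 (adjusted p = 4.7e-05), the latter on 2 libraries per group.

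Other name-checked genes, chosen after their values were seen, also differed. Pdk4, a kinase that holds back pyruvate oxidation, had a log2FC of 2.02 with adjusted p = 0.0075. Nr4a3, an orphan nuclear receptor, had 1.09 with adjusted p = 0.0013, and Tgfbr1, a TGF-beta receptor, 0.90 with adjusted p = 0.0082. Rps20 averaged 8624 CPM in vector and 5611 CPM in PSGL1_KO libraries, a log2FC of -0.62 with adjusted p = 0.045. It had -0.87 within file number 7 (adjusted p = 0.0019) and 0.03 within file number 3 (adjusted p = 0.93), and it did not pass without any one of vector replicates 2 to 7 or PSGL1_KO replicates 1, 4, 5 and 6, with adjusted p from 0.051 to 0.11. Nor did Rps20 pass with the replicate number as a block, with a log2FC of -0.59 and adjusted p = 0.069.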
